A study of Mus musculus with 12 samples.

How the data were processed

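RNA from sciatic nerve lysates and from laser-captured motoneurons of wild type mice and of mice lacking exon 5 of Gdap1 was measured on 12 Affymetrix 3' expression arrays, 3 for each tissue and genotype. Per the labels, each array is a biological replicate from a mouse aged 2 months, 20 ng of RNA was amplified and labelled with biotin, and a different column kit was used for each tissue. The design text states that RNA was taken from 5 mice and that samples were selected by the amount and quality of their RNA. The 5 cannot be the total for all 12 arrays if replicates of a group are different mice, given the sex-linked transcripts described below. Whether a nerve and a motoneuron array came from the same mouse is not stated there.

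The deposited values are log2 expression values per probe set. The log2 scale was read from the values, with none missing. Affymetrix Expression Console 1.1 made them, per the submitters' processing notes. The summarization method and background correction are not given in the sources used here. Quantiles nearly coincided between arrays of a tissue, with ranges of at most 0.113, while the medians of the tissues differed by 1.77. The tissues were therefore read as normalized separately, so a level in one tissue is not on the same scale as a level in the other. Arrays have no read depth, and their number limits the precision.

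Of 45101 probe sets, 64 control probe sets were left out and 45037 were tested. Platform annotation gave 34945 of these exactly 1 gene symbol, 932 several and 9160 none; the last are unnamed here, not without a gene. Symbols were updated by gene identifier from the RefSeq table of assembly GRCm38.p6, which held 34741 of the probe sets with 1 symbol, and that table also gave the order of genes on chromosomes. No coordinates were used. No gene was named from a probe set with several symbols. For gene lists, each of 18194 genes was represented by its probe set with the highest mean; 9009 genes had more than 1, and those of Gdap1 differed from one another in level and change.

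Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend), with two-sided p-values and Benjamini-Hochberg adjustment over all tested probe sets at a threshold of 0.05. The comparisons were the genotype in nerve, the genotype in motoneurons, the difference of those effects as an interaction over 12 arrays, and motoneurons against nerve in wild type. Of 28 gene lists, 27 with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison. The remaining list had 4. Of 761 list entries, 702 were measured. Exact permutation tests were two-sided, and 3 arrays against 3 cannot give a p below 0.1.

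The comparisons, their tests, the lists and the rule for named genes were chosen before the data were examined. The rule names every Gdap1 and Gdap1l1 probe set, the genes with the largest change among those that passed and whose groups did not overlap, up to 4 members of each list by smallest unadjusted p, and sex-linked transcripts. Where fewer than 10 genes passed, it names those and then the 8 higher and 8 lower genes with the smallest unadjusted p and a mean above the median. Alternatives covered normalization, filtering, array weights, covariates, the arrays fitted together and each array left out. On values simulated from the real means and spreads, with 66 or 67 of 45037 probe sets changed at each size, log2 changes of 2 were recovered for 95.5% in nerve, 90.9% in motoneurons, 60.6% in the interaction and 92.4% between tissues. Changes of 1 were recovered for 46.3%, 28.4%, 11.9% and 31.3%, in the same order. The simulated noise was normal and independent between probe sets, with the moderated spread, so these shares can overstate recovery in the real values. In nerve, an estimated difference of 2.02, that of Vxn, did not pass (adjusted p = 0.716 by limma). It was picked for its small p, so it does not measure recovery. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.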

Results

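Gene expression was compared between wild type mice and mice lacking exon 5 of Gdap1, which encodes a protein of the outer mitochondrial membrane whose mutations underlie a form of Charcot-Marie-Tooth neuropathy. Sciatic nerve, rich in Schwann cells, and motoneurons captured by laser were each profiled on 3 arrays per genotype. The question was which transcripts differ in mice without Gdap1. Median log2 values of the arrays lay between 8.29 and 8.40 in nerve and between 6.54 and 6.59 in motoneurons, and no pair of arrays held identical values.

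Gdap1 (Entrez gene 14545, chromosome 1) was still measured in knockout motoneurons, by probe sets that the design text places in exons 4 and 6, outside the deleted exon, so these values check nothing about the labels. Its 4 probe sets are given in order of their level in wild type motoneurons. The first read 13.31 ± 0.071 (SD, n = 3) in knockout and 13.34 ± 0.040 (SD, n = 3) in wild type. The second differed by 0.34 (SE 0.15, adjusted p = 0.318 by limma), the third by 0.70 (SE 0.16, adjusted p = 0.123) and the fourth by -0.13 (adjusted p = 0.819). The paralog Gdap1l1 differed by 0.34 (SE 0.082, adjusted p = 0.130) and, by its other probe set, by 0.21 (adjusted p = 0.320). None of these passed, and in nerve every Gdap1 and Gdap1l1 probe set had an adjusted p of 1.

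Sex-linked transcripts divided the arrays otherwise than by genotype. In nerve, Xist, which is transcribed from the inactive X chromosome, read 12.58 in wild type replicate 2 and 12.80 in knockout replicate 3 and at most 4.29 in the other arrays, by 1 of its probe sets. The Y-linked gene Eif2s3y read 4.71 and 5.39 in those arrays and at least 12.58 in the others. In motoneurons, knockout replicate 2 had the only low Xist value, 3.21, and the only high Eif2s3y value, 10.95. Same-numbered nerve and motoneuron arrays thus cannot all come from the same mouse. Sex was also not balanced between genotypes in motoneurons, since the only array with low Xist was a knockout array. It is among the arrays whose removal ended the astrocyte and endothelium calls below.

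In wild type mice, 36992 of 45037 probe sets differed between motoneurons and nerve. Trhr, the receptor for thyrotropin-releasing hormone, was higher in motoneurons by 10.08 (SE 0.20), Fstl5 by 9.72 and Gabra5, a GABA receptor subunit, by 9.55. In the other direction, Egr2, a regulator of myelination, differed by -11.17 (SE 0.18), the myelin protein gene Pmp2 by -11.13 and the collagen gene Col3a1 by -11.23. All of these had an adjusted p of at most 8.06e-08. Gdap1 was higher in motoneurons by 7.41 (SE 0.23, adjusted p = 1.20e-07) by its first probe set and Gdap1l1 by 5.34 (adjusted p = 9.91e-08). The fourth Gdap1 probe set gave -0.33 (adjusted p = 0.0860), which became 1.42 when the arrays were quantile normalized together and 1.43 when they were centred on their medians.

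Of 20 measured motoneuron markers, 17 were higher and 2 lower in motoneurons, with the same counts adjusted over the list alone and a median of 3.97 (camera adjusted p = 1.77e-12). Examples are the neurofilament genes Nefm and Nefl, at 6.29 and 4.88, and the motoneuron regulator Mnx1, at 6.30. Of 32 tubulin and axonal transport genes, 25 were higher and 6 lower, again also adjusted over the list alone, with Tubb3 at 6.87 (camera adjusted p = 2.63e-11). All 22 fibroblast genes, all 20 endothelium and mural genes and all 24 microglia and macrophage genes were lower over all genes and adjusted over the list alone, with medians of -7.71, -5.08 and -5.32, which stayed negative with the other scalings. All 24 myelin genes were lower as well, with a median of -3.52, but after centring 6 of them were higher and 17 lower, with a median of -1.76. Of 23 genes of immature, repair and non-myelinating Schwann cells, 8 were higher and 12 lower, with a median of -0.66, which turned positive with the other scalings, with 10 higher and 8 lower after quantile normalization and 13 higher and 7 lower after centring. Other spinal cord cell types were not lower throughout. Of 15 astrocyte genes 7 were higher and 6 lower (median 0.70, camera adjusted p = 0.01995). Of 16 spinal interneuron genes 8 were higher and 4 lower (median 1.01, camera adjusted p = 0.000109). Of 18 oligodendrocyte genes 8 were higher and 9 lower (median -0.64). In motoneuron arrays of both genotypes the astrocyte and oligodendrocyte lists had mean levels of 10.27 and 10.5, above the array medians. Camera called 14 of 27 lists, none with an estimated correlation, where the smallest adjusted p was 0.116.

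In total 6419 probe sets were higher and 30573 lower in motoneurons, so 17.4% of the calls were higher. That split depends on the separate normalization of the tissues: it was 54.6% after quantile normalization of the wild type arrays of both tissues together and 69% after centring, with the median of all probe sets moving from -1.09 to 0.15 and 0.67. Tissue and extraction kit also cannot be told apart. Sex was not balanced either: Xist was high in every wild type motoneuron array but, of the wild type nerve arrays, only in replicate 2.

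In motoneurons no probe set passed between genotypes. Among the genes with the smallest p and a mean above the median, Rhob, a small GTPase, had a knockout minus wild type log2 difference of -0.68 (SE 0.069, adjusted p = 0.0903), Calr, a calcium-binding chaperone of the endoplasmic reticulum, of -0.69, and Api5, an inhibitor of apoptosis, of -0.60. Klhl2, Eif4g2, Septin7, Slitrk4 and Morf4l2 lay between -0.90 and -0.53. On the other side were Itga9, an integrin subunit, at 2.32 (SE 0.29, adjusted p = 0.0904), Blvra, which reduces biliverdin, at 0.41, Chchd10, a mitochondrial protein, at 0.43, and Ptpa, Prkcz and Mark1 at 0.44, 0.41 and 0.51.

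The mitochondrial lists held members on both sides. Of 71 measured respiratory chain subunits, 44 had higher and 27 lower values, none passed over all genes, and 5 higher and 3 lower passed adjusted over the list alone; Uqcrb differed by -0.46 (adjusted p = 0.110) and Ndufa7 by 0.28 (adjusted p = 0.108). Among 29 genes of mitochondrial fission and fusion none passed either way, and Dnm1l, the fission GTPase, differed by -0.31 (adjusted p = 0.178). Of 45 genes of redox defence, none passed over all genes and 3, all lower, passed adjusted over the list alone; catalase (Cat) differed by -0.56 (adjusted p = 0.108) and glutathione reductase (Gsr) by -0.57 (adjusted p = 0.125). Camera called none of these lists, with adjusted p = 0.220, 0.752 and 0.896. Fry, testing each list for change in either direction and not against other genes, called the respiratory chain (adjusted p = 0.0384) and fission and fusion (adjusted p = 0.0359) but not redox defence (adjusted p = 0.115), where 17% of all probe sets had an unadjusted p under 0.05. The medians of the fission and redox lists, 0.021 and 0.013, became -0.0036 and -0.012 after centring. Of 20 motoneuron markers, Ret at -0.35 and Isl1 at -0.51 passed adjusted over the list alone and none over all genes, and the list was not called (adjusted p = 0.0943).

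Camera called 3 lists in motoneurons, each toward lower values in knockout. For 15 astrocyte genes the median was -0.23 (adjusted p = 0.0145), with none passing over all genes and 4 lower adjusted over the list alone; the transporter genes Slc4a4 and Slc1a3 differed by -0.98 and -0.81. For 20 endothelium and mural genes it was -0.38 (adjusted p = 0.0495), with none passing either way and Rgs5 at -0.79. Of other cell type lists, which were not called, oligodendrocyte genes had a median of -0.28 with 14 of 18 lower (adjusted p = 0.0724), immature and repair Schwann cell genes of -0.20 with 17 of 23 lower (adjusted p = 0.109) and microglia and macrophage genes of -0.028 with 15 of 24 lower (adjusted p = 0.809). For 43 genes near Gdap1 on chromosome 1 the median was -0.14 (adjusted p = 0.00428), with 8 lower and 1 higher adjusted over the list alone and none over all genes; Vcpip1 differed by -0.43, Ube2w by -0.76, Rrs1 by -0.75 and Adhfe1 by -1.09. With an estimated correlation no list was called (adjusted p = 0.648 for each of the 3), nor by fry for direction (adjusted p = 0.101 to 0.250 for these). The astrocyte call ended without wild type replicate 3 (adjusted p = 0.393), without knockout replicate 2 (0.106), with the mean of a gene's probe sets (0.0765) and among brighter probe sets (0.0536), over a range of 0.000181 to 0.648, and its median was -0.098 with that mean and -0.36 without knockout replicate 1. The endothelium call ended without those arrays (0.393 and 0.0814), after centring (0.0675), among brighter probe sets (median -0.23, 0.294) and by fry in either direction (0.459), over a range of 0.00249 to 0.648. It also ended without Gdap1 and 40 or 100 genes on each side (0.0716 and 0.0687). Its median stayed at -0.38 there, so that loss does not tie the list to genes near Gdap1. The median of the genes near Gdap1 was -0.24 without wild type replicate 3 and -0.070 with the mean of a gene's probe sets. Without Gdap1 and 40 genes on each side it was -0.069 and the call ended (camera adjusted p = 0.533). That setting removed most of the list itself, so this lost call decides nothing about these genes.

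By limma, 0 probe sets passed in motoneurons, the smallest adjusted p was 0.0790, and 7665 had an unadjusted p under 0.05 where chance gives 2252. For 22.5% of probe sets the groups did not overlap, where chance gives 10%. The count rested on wild type replicate 3, whose mean correlation across probe sets was 0.9802 with knockout arrays and 0.9699 with its own group: without it 4646 probe sets passed, 2107 higher and 2539 lower. It was also 61 among brighter probe sets, 828 with all 12 arrays in 1 fit and 2929 with array weights, and 0 under the other settings. Measures of the arrays moved with genotype too: the spiked bioB control differed by -0.54 and 18S RNA by 0.55 (exact permutation p = 0.1 each, the smallest possible). In wild type replicate 3, 18S RNA read 14.64, near the 14.66 to 14.67 of the knockout arrays and above the 13.94 and 13.77 of the other wild type arrays. With the beta-actin 3' to 5' ratio as a covariate, a setting chosen after seeing the data, 4048 probe sets had an unadjusted p under 0.05, but with the Gapdh 3' to 5' ratio, a planned setting, 7655 did. With the Xist level as a covariate, also planned, 6491 did. With 1 array left out the number ranged from 5057 to 10986.

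**Figure D1:**
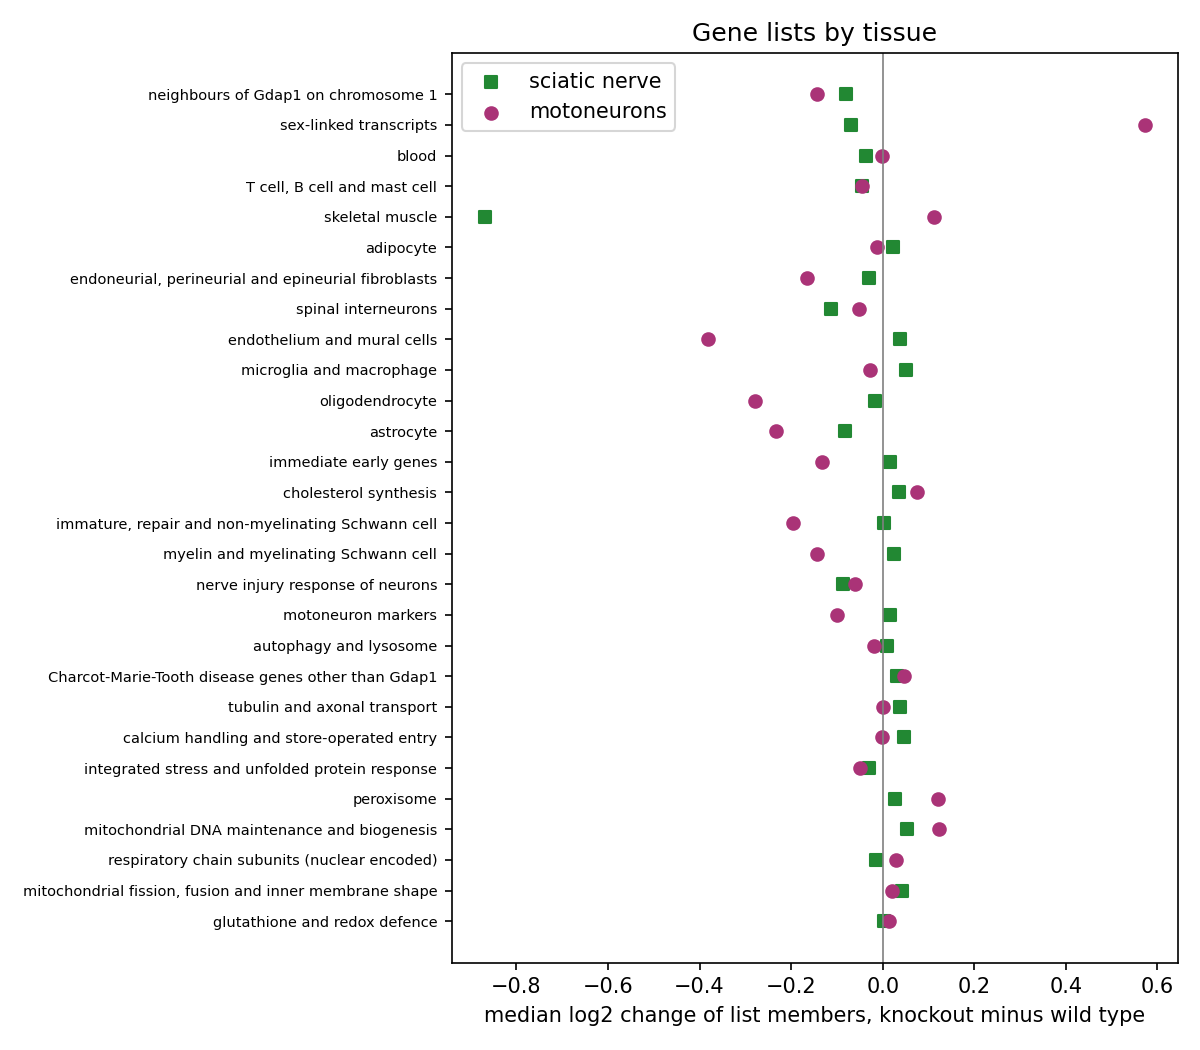
Median log2 change of the members of each gene list, knockout minus wild type, with sciatic nerve as squares and motoneurons as circles, 3 arrays per group. Skeletal muscle in nerve lies at -0.87 and endothelium in motoneurons at -0.38.

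In sciatic nerve no probe set passed between genotypes. The smallest p belonged to Vxn on chromosome 1, at 2.02 (unadjusted p = 1.59e-05 by limma), with a mean in nerve not above the median of all probe sets. Of the 8 higher and 8 lower genes with the smallest p among those with a mean above the median, 6 lie on chromosome 1: Rrs1, a ribosome assembly factor, differed by -0.55 (SE 0.081, unadjusted p = 0.000231 by limma), the noncoding RNA gene Snhg6 by -0.52, Tram2 by -0.38, Csrp1 by 0.47, Mia3 by 0.34 and Ncoa2 by 0.80, although another Ncoa2 probe set gave -0.068. Csrp1 and Mia3 are not among the 80 measured genes within 40 on each side of Gdap1, and the number on chromosome 1 was not tested against chance. Ccl17, a chemokine, differed by 0.76, and the muscle genes Myh1 and Ldb3 by -3.52 and -1.36. In motoneurons Rrs1 and Snhg6 differed by -0.75 and -0.57.

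Camera called 2 lists in nerve, both toward lower values in knockout. For 23 skeletal muscle genes the median was -0.87 (adjusted p = 0.00419; adjusted p = 0.961 with an estimated correlation), with 19 lower and 4 higher values and none passing over all genes or adjusted over the list alone. Their mean level was 9.89 ± 0.45 (SD, n = 3) in knockout and 10.78 ± 2.08 (SD, n = 3) in wild type, a difference within the spread between arrays (exact permutation p = 0.5). The muscle call ended without wild type replicate 1, the array with the highest level (median 0.077, adjusted p = 0.787), without wild type replicate 3 (median -0.44, 0.0719) and without knockout replicate 2 (median -0.52, 0.117), over a range of 1.97e-24 to 0.977, and the median was -2.36 without wild type replicate 2 and -2.39 without both Xist-high arrays. For the 43 genes near Gdap1 the median was -0.081 (adjusted p = 0.00923; adjusted p = 0.419 with an estimated correlation), with 31 lower and 12 higher values, none passing over all genes and 1 lower adjusted over the list alone. That call ended without wild type replicate 1 or 3 (0.227 and 0.0761) and with the mean of a gene's probe sets (0.0652), over a range of 0.000331 to 0.970, and the median was -0.13 without wild type replicate 2, -0.047 without knockout replicate 1 and -0.12 after centring. It also ended without Gdap1 and 40 genes on each side (0.278), with a median of -0.086. That setting removed most of the list itself, so this lost call decides nothing about these genes. By fry, in direction or either way, neither list was called (adjusted p = 0.867 to 0.977). The lists of myelin, the respiratory chain and redox defence were not called. Their medians were 0.024 (adjusted p = 0.280) for 24 myelin genes, -0.014 (adjusted p = 0.628) for 71 respiratory chain subunits and 0.0023 (adjusted p = 0.861) for 45 redox genes, and after centring those for myelin and redox became -0.017 and -0.039.

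**Figure D2:**
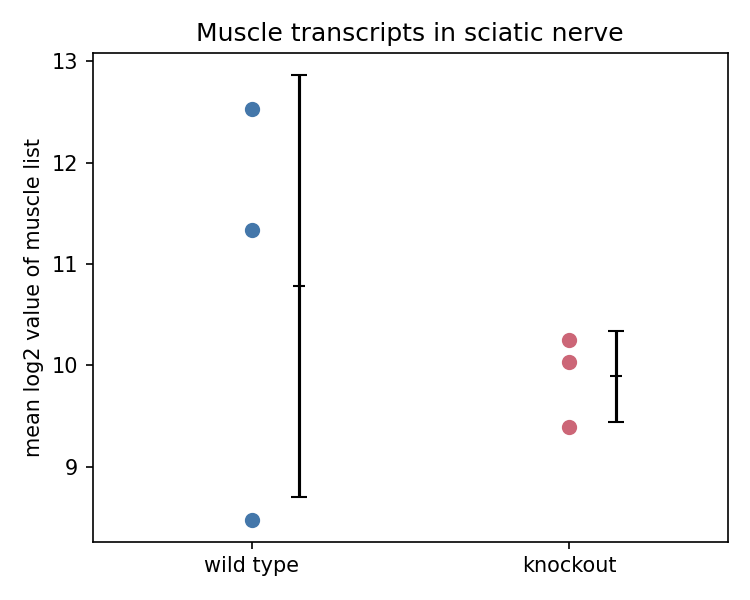
Mean log2 value of the 23 skeletal muscle genes in each sciatic nerve array, with the mean and SD of each genotype (n = 3). Wild type arrays lie between 8.48 and 12.53 and knockout arrays between 9.39 and 10.25.

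By limma, 0 probe sets passed in nerve, the smallest adjusted p was 0.716, and 1040 had an unadjusted p under 0.05, fewer than the 2252 that chance gives, although the number was 1740 without wild type replicate 2, 1758 with the replicate number as a block and 3051 without both arrays with a high Xist level. Groups did not overlap for 7.26%, where chance gives 10%. Under the other settings the count stayed at 0, except that Vxn passed with all 12 arrays in 1 fit, at 2.02 (SE 0.21, adjusted p = 0.0193); Vxn lies near Gdap1 and was singled out here after its value was seen. The spiked bioB control differed by -0.92 between genotypes in nerve (exact permutation p = 0.1, the smallest possible).

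**Figure D3:**
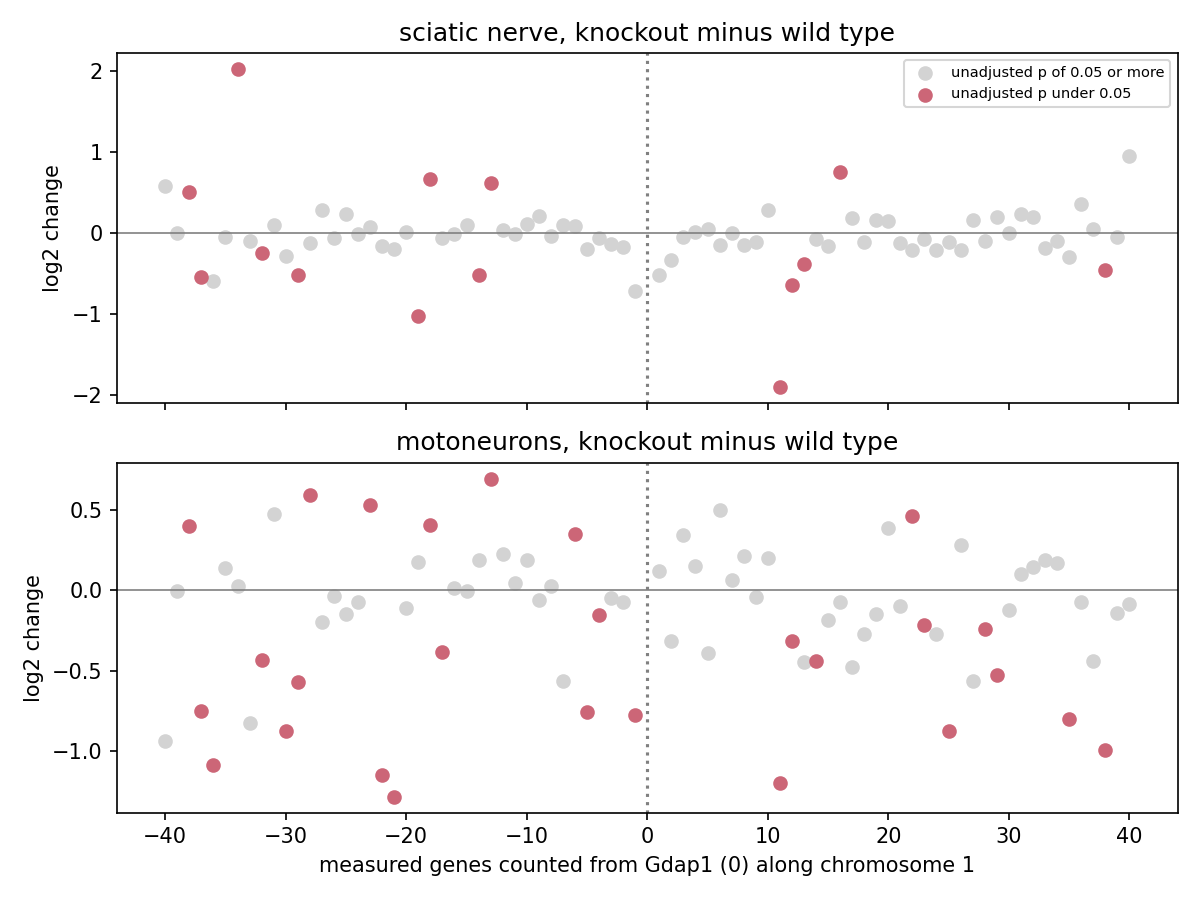
Log2 change, knockout minus wild type, of 80 measured genes on chromosome 1 in order from Gdap1 at 0, in sciatic nerve and motoneurons, whose vertical scales differ. Coloured points have an unadjusted p under 0.05, 14 in nerve and 27 in motoneurons.

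The genotype effect was not shown to differ between tissues for any probe set. Among genes with a mean above the median, Cav1, a protein of caveolae, had the smallest p, with a motoneuron minus nerve difference of -1.65 (SE 0.22, adjusted p = 0.173), from -1.76 in motoneurons and -0.11 in nerve. Vxn came next among these (adjusted p = 0.206), at 0.027 in motoneurons and 2.02 in nerve. Camera called 4 lists in the difference: skeletal muscle toward higher values (adjusted p = 0.00452), and myelin (adjusted p = 0.00870), endothelium (adjusted p = 0.00870) and oligodendrocyte genes (adjusted p = 0.0287) toward lower values. No member of these lists passed over all genes or adjusted over the list alone. With an estimated correlation none of the 4 lists was called (adjusted p = 0.835, 0.715, 0.715 and 0.835, in that order), nor among brighter probe sets (0.0555, 0.0555, 0.0951 and 0.145), nor by fry for direction (0.507 to 0.725) or either way (0.238 to 0.615).

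By limma, 0 probe sets passed in the interaction and 3398 had an unadjusted p under 0.05. With array weights 5796 did. Without motoneuron wild type replicate 3 the count was 238, with 6311 at an unadjusted p under 0.05, and all 4 list calls ended (adjusted p = 0.0611 for muscle, 0.186 for myelin, 0.299 for endothelium and oligodendrocyte). Without nerve wild type replicate 2, probe sets of Myh1 and Myhas passed, and without motoneuron wild type replicate 1, those of Cav1 and Col1a1, these genes being named after their values were seen. The muscle call also ended without nerve wild type replicate 1 (0.236) and the endothelium call without nerve knockout replicate 1 (0.0501). The myelin call ended without nerve wild type replicates 1 and 2 or knockout replicate 3 (0.0695, 0.0821 and 0.0627). The oligodendrocyte call ended without nerve wild type replicate 1 or knockout replicate 1 and without motoneuron wild type replicate 1 or knockout replicate 2 (0.113, 0.195, 0.152 and 0.288), and with the mean of a gene's probe sets (0.0557). Over all alternatives the adjusted p ranged from 1.30e-25 to 0.835 for muscle, from 0.000127 to 0.715 for myelin, from 0.000113 to 0.715 for endothelium and from 0.000113 to 0.835 for oligodendrocyte genes.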

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

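Among the tests in this part, the comparison of nerve with motoneurons for an array batch, the beta-actin ratio as a covariate and the sorting of splits by the genotypes they keep together were chosen after the result was seen. Camera called 4 gene lists in the interaction, none of them with an estimated correlation (adjusted p = 0.715 to 0.835) or among brighter probe sets (0.0555 to 0.145). The median motoneuron minus nerve difference was 1.16 for skeletal muscle, -0.19 for myelin, -0.29 for oligodendrocyte genes and -0.35 for endothelium and mural genes. These medians rested on single arrays: muscle was 0.24 without nerve wild type replicate 1 and 2.36 without replicate 2, myelin -0.11 without motoneuron knockout replicate 2, and endothelium -0.19 without motoneuron wild type replicate 3. Oligodendrocyte genes were at -0.081 without motoneuron wild type replicate 1, -0.12 without motoneuron knockout replicate 2 and -0.17 without nerve knockout replicate 1. Within each tissue, the genotype median of the muscle list was -0.87 in nerve and 0.11 in motoneurons, so its difference came mostly from nerve. The mean level of that list in motoneuron arrays was 6.04, under the array medians. Of 100 splits of the arrays within tissues, 73 called at least the 4 lists observed, up to 12, and 22 gave at least the 3398 probe sets observed at an unadjusted p under 0.05, up to 9425. Of those 22, 12 keep the motoneuron genotypes together, the real split and the one with 9425 among them, and so carry that difference. Of 80 splits that keep the genotypes of neither tissue together, 62 called as many lists, up to 12, and 10 gave as many probe sets, up to 7087, so chance is not excluded for either count.

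Of 23 skeletal muscle genes 19 had lower and 4 higher values in knockout nerve, none passing, and the median of -0.87 was 0.077 without wild type replicate 1. Muscle adhering to the dissected nerve is a candidate explanation: within genotypes these genes varied together between arrays, with a median pairwise correlation of 0.921, which none of 1000 random lists of like level reached. Genes in a random list share no cell type, so this comparison cannot tell adhering muscle from another source of muscle transcripts. The level varied more among wild type arrays, from 8.48 to 12.53, than between the genotypes, whose means differed by -0.89. Not every member varied widely between arrays: Tnnt3 and Tnnc2 ranged from 11.08 to 14.94 and from 8.53 to 14.97, but Tnni1, Tnnt1 and Myh7 only from 8.89 to 9.12, 9.17 to 9.58 and 6.78 to 7.11, and Tnnc1 from 9.97 to 11.17. An effect of the genotype on muscle transcripts stays open and was not tested apart from it.

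Motoneurons held 7665 probe sets at an unadjusted p under 0.05, 1 of 10 splits reached that count, the real one, and the highest other gave 4231; the splits are too few for a share under 0.05. With the mean level of 77 glial, microglial and endothelial genes as a covariate the count was 7009, and 7653 without it, both without those genes. This argues against other cells whose content follows that pooled level as the whole cause. However, the level differed by -0.22 between genotypes and correlated with genotype at -0.629. A single cell type stays open. The microglia and endothelium lists had mean levels of 6.49 and 6.76, near the array medians, and their median changes differed (-0.028 and -0.38), so 1 pooled mean cannot stand for each type. A wrong genotype label on wild type replicate 3 is argued against too: on the genes around Gdap1, weighted by their nerve changes, it lay at -0.193, between the other wild type arrays at -0.283 and -0.0961 and apart from the knockout arrays at 0.135 to 0.252. An array batch cannot be told apart from the genotype, because no batch is given that holds both: the bioB and bioC controls differed by -0.92 and -0.52 in nerve and -0.54 and -0.25 in motoneurons, bioD and cre by -0.36 and -0.090 in nerve and -0.40 and -0.12 in motoneurons, while nerve gave 1040 such probe sets, or 3051 without the Xist-high arrays. An effect of the genotype and a difference in RNA quality stay open, the count being 4048 with the beta-actin 3' to 5' ratio as a covariate but 7655 with that of Gapdh. The 18S RNA level was not used as a covariate. It read 13.94 and 13.77 in wild type replicates 1 and 2, 14.64 in wild type replicate 3 and 14.66 to 14.67 in knockout arrays. Without wild type replicate 3, where 4646 probe sets passed, 18S RNA and genotype therefore cannot be told apart.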

How the results depend on the processing

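The settings that leave out the Xist-high nerve arrays, use the beta-actin ratio, leave out genes around Gdap1 or rescale the arrays for list tests were chosen after seeing the data. A pseudocount was not run, since the values are log2. Of 3033 values of named genes under alternatives, 2830 kept their direction and side of the threshold, 188 newly passed, 76 of them without motoneuron wild type replicate 3 and 69 with array weights, and 15 changed sign. The cause was not tested. Apart from Gdap1 and Gdap1l1, the genes counted here were picked by their p or change in the same data. The kept share therefore says little about stability, and sign changes confined to Gdap1 and Gdap1l1 do not mark these genes as less stable. Those that changed sign were Gdap1 or Gdap1l1 values, none past the threshold in nerve, motoneurons or the interaction, with Gdap1 probe sets in order of level. In nerve, the less bright Gdap1l1 probe set was -0.0019 after centring, and with an array left out the second Gdap1 probe set ranged from -0.42 to 0.25 and the third from -0.024 to 0.23. In motoneurons, the first was 0.0022 after quantile normalization, 0.0034 with array weights, 0.0099 with Xist as a covariate and -0.050 to 0.015 with an array left out, and the fourth 0.058 with Xist and -0.28 to 0.050 with an array left out. In the interaction the fourth ranged from -0.20 to 0.13 with an array left out, and between tissues it was 1.42 and 1.43 after quantile normalization and centring. Counts of probe sets in nerve were 1 with all 12 arrays in 1 fit and otherwise 0. In motoneurons they were 61 above the median level, 2929 with array weights, 828 with all 12 arrays and 0 to 4646 with an array left out, and in the interaction 0 to 238 with an array left out. Between tissues, 18336 passed above the median level and 14760 with 1 probe set per gene, where fewer were tested. List calls in nerve numbered 0 with an estimated correlation and with fry either way, 1 with the mean of all probe sets, 4 with the replicate block, 7 without the Xist-high arrays, 1 without 40 or 100 genes on each side of Gdap1 and 0 to 6 with an array left out. Leaving out those 40 or 100 genes takes away most or all of the list of genes near Gdap1, in either tissue. In motoneurons they numbered 0 with an estimated correlation and with fry for direction, 9 with fry in either direction, 1 above the median level, 5 with the block, 1 without 40 or 100 genes on each side and 1 to 6 with an array left out. In the interaction they numbered 0 with an estimated correlation, with fry and above the median level, 6 with the block and 0 to 10 with an array left out. Between tissues they numbered 0 with an estimated correlation, 24 with fry for direction, 27 in either direction and 14 with the block. The replicate numbers were not taken to pair the arrays, which the design does not state. Deviations of same-numbered wild type and knockout arrays correlated across probe sets at 0.0719, 0.473 and 0.558 in nerve. Arrays of different numbers there reached at most 0.0365. Each nerve array was best with its own number, a hint at pairs that the main nerve test ignores, although the first is under 0.1. In motoneurons the correlations were 0.192, -0.13 and -0.156, and different numbers reached up to 0.266. With the block, 0 probe sets passed for the genotype in each tissue and the interaction, with 1758, 6773 and 4274 at an unadjusted p under 0.05 in nerve, motoneurons and the interaction, and 36402 passed between tissues.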

Other observations

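Among the tests in this part, the share of genes per window, the windows of 20 and 100 genes on each side, and taking the counting spread into account for the median t of windows were chosen after the result was seen. In motoneurons, genes of lists not described so far differed without passing: the immediate early genes Klf6 and Fos by -1.19 (adjusted p = 0.107) and -0.80 (adjusted p = 0.191), the mitochondrial protease Lonp1 by 0.49 (adjusted p = 0.115) and the mitochondrial RNA polymerase Polrmt by 0.50 (adjusted p = 0.123). Fry, testing for change in either direction and not against other genes, called 9 lists in motoneurons, where 17% of all probe sets had an unadjusted p under 0.05, and none in nerve. Among the 9 were tubulin and axonal transport (adjusted p = 0.00497) and peroxisome (adjusted p = 0.0195), neither of which camera called (adjusted p = 0.648 and 0.398).

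Of 80 measured genes within 40 on each side of Gdap1, 17.5% had an unadjusted p under 0.05 in nerve, where the median of 210 other windows was 1.23% and the highest 8.64%, while in motoneurons the share depended on the window size: 33.8% against a median of 21%, with 1 other window as high, but with 20 genes on each side 25% against 19.5%, with 105 of 429 as high. A candidate explanation is a strain variant carried along with the targeted gene, but its test did not decide, since the changes in nerve and motoneurons correlated across these genes, which are not independent replicates, at 0.347 and 7.14% of other windows were as high, above a bound of 5%. With 20 and 100 genes on each side 1.63% and 3.75% were as high, so that outcome depends on the window size. An array batch as the cause of the lower values stays open, since 0.952% of other windows had a median t as low in both tissues, under a bound of 1% but with an upper 95% limit of 3.40%, and with 20 and 100 genes on each side 10.5% and 2.50% did; only for the share in nerve, which no other window reached at any of the 3 sizes, is a batch argued against. An effect of losing Gdap1 on its neighbours stays open and was not tested apart from a strain variant.

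For the other comparisons the splits of the arrays are too few for a share under 0.05. In nerve, 9 of 10 splits gave at least the 1040 probe sets observed, up to 6553, and all 10 called at least the 2 lists observed, up to 12. In motoneurons, 7 of 10 called at least the 3 lists observed, up to 8. Between tissues, 1 of 10 splits, the real one, gave 36992 calls and the highest other 0, and 4 of 10 called at least the 14 lists observed, up to 15. The nerve split with 6553 probe sets, several times the real count, points to a structure of the arrays other than genotype. It keeps both number 2 arrays together and both number 3 arrays together. On the first principal component of nerve (46.2% of the variance), number 2 arrays lay at -36.36 in wild type and -28.55 in knockout. Number 3 arrays lay at 30.71 and 21.70, and number 1 arrays between, at 12.26 and 0.242. That order follows the replicate number, which the main fit leaves out.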
